A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

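Whole-genome sequencing libraries of Saccharomyces cerevisiae W303-1a were used, 1 per strain label (WT, orc2ΔN200 and orc2-I194E) and time (0 min in G1 phase and 30 min after release into S phase), 6 in all. Per the labels' protocols, cells grown in YPG were arrested with α-factor, shifted to YPD with nocodazole for G2/M arrest and depletion of orc2-1, arrested again with α-factor and released, and sodium azide stopped elongation at harvest. Genomic DNA was sequenced on a DNBseq platform.

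The deposited files give a whole-number count per 1-kb bin of the genome, with bins of no count left out. The submitters' processing notes name Bowtie2 2.5.3, Picard 2.27.5, SAMtools 1.18, bedtools 2.31.0 and R 4.3.0 and the genome build sacCer3, without the role of each tool. Filters, the treatment of duplicates, and whether reads or fragments were counted are not stated there. The counts carried no scaling, since each library summed to a different whole number.

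Everything from here on was computed from these counts with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Library totals lay between 3235720 and 3376203. A nuclear bin was kept if it lay outside the rDNA array (451001 to 490000 on chromosome XII), had a count above 0 in every library, and had G1 counts between 0.3 and 3 times the library median. This kept 11273 of 11579 nuclear bins, with a median of 255 to 273 counts each. Of the nuclear bins, 116 had no count in at least 1 library. The share of a bin is its count divided by the total over kept bins, and the profile of a strain is the log2 of its S share over its own G1 share, so a value of 0 is the genome mean. Profiles were smoothed with a centred running mean of 5 kb, or of 21 kb for hills, valleys and regions.

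Genes and chromosome arms came from a gene table of assembly R64, the assembly of sacCer3, with 6477 genes. The planned design compared heights at annotated origins of replication and at lists of early, late and silent origins. The annotation used names no origins, so no member of these lists could be placed, and the planned fallback was used: local maxima of the WT profile with a prominence of at least 0.1, taken over the 5 kb centred on each and named by the nearest gene. Centromeres were placed in the gap between the innermost genes of the left and right arms, as their locus tags give them (gaps of 0.631 to 2.54 kb). Subtelomeric bins lay within 30 kb of an end and centromeric bins within 20 kb of a centromere.

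With 1 library per strain and time, no strain's ratio of S to G1 was replicated. No test across samples was planned or run, and no p-value is given. A comparison of WT with the mutants taken as 1 group would have had 1 residual degree of freedom. Counting error came from Poisson intervals and from 200 Poisson resamplings of all counts, at 95%, and covers counting error only. Ratios of G1 libraries of different strains served as the background without replication. The median over sites was set against 10000 random sets of positions. That over ends or centromeres was set against 10000 rotations of their positions, made separately within each chromosome. As both mutants were compared with the same WT libraries, 100 draws of 3 strains with the same expected profile were run through the same steps. These draws hold counting noise only, without variation between cultures or in the timing of release. Copy levels at ORC2 and LEU2 were taken relative to the mean of the bins within 20 kb, and in a planned form relative to the library median.

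The 5-kb sites, the site classes, the amplitude, the correlations, the copy checks and their alternatives were chosen before the data were examined. The 21-kb hills with a prominence of 0.2, the regions, the comparison over all bins near ends and centromeres, the exchange of labels, the partial correlations, the search for bins that crossed between WT and orc2-I194E, and sites from pooled or mutant profiles were chosen after seeing the data. The rule for named sites, also fixed before, was the listed origins that the annotation holds (none), the 10 highest in WT, the 10 largest falls and the 5 largest rises in each mutant, and ORC2. Other genes, hills, ends and regions in the text were chosen after their values were seen.

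The steps were tested on simulated data first, with known hills placed in a WT profile of 11273 bins and lowered in the mutants. For hills of 0.4, the median height at 66 simulated positions was 0.29 and came back as 0.28, and simulated changes of -0.15 (orc2ΔN200) and -0.30 (orc2-I194E) came back as -0.13 and -0.27. For hills of 0.2, a height of 0.11 at 67 positions came back as 0.099. The 21-kb setting found 77.3% of hills of 0.4, 17.9% of those of 0.2 and 0% of those of 0.1, with 0 of its 65 calls farther than 10 kb from a simulated hill. The 5-kb setting found 90.9%, 85.1% and 73.1%, but 234 of its 457 calls were farther than 10 kb from one. At those 457 calls the change in orc2ΔN200 came back as -0.085 where 0.015 was simulated, which is the effect of choosing sites on noise. A simulated shift of 0.095 at ends came back as 0.090.

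A correction for GC content was planned for the case that a genome sequence was at hand; none was used here, so it was not run. The mitochondrial genome and the rDNA bins were left out of the profiles and are given on their own.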

Results

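Copy number along the budding yeast genome was measured by whole-genome sequencing of synchronised W303-1a cells, a standard laboratory strain. ORC2 encodes a subunit of the origin recognition complex, which binds replication origins and loads the MCM helicase there in G1 phase. The libraries carried 3 strain labels: WT (full-length Orc2), orc2ΔN200 (the first 200 residues of Orc2 removed) and orc2-I194E (a single residue of that stretch changed). Each strain was sampled at 0 min, in G1 phase under α-factor, and 30 min after release into S phase. There were 6 libraries, 1 per strain and time, and so no replicate. Intervals given below are 95% intervals that cover counting error only. The question was which parts of the genome had gained copies by 30 min, and how this differed when the N-terminal part of Orc2 was missing or altered.

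The libraries held between 3235720 and 3376203 counts in 1-kb bins, and depth hardly differed between them. The totals were 3310004 (WT, G1), 3354757 (WT, S), 3341976 (orc2ΔN200, G1), 3288179 (orc2ΔN200, S), 3376203 (orc2-I194E, G1) and 3235720 (orc2-I194E, S). A kept nuclear bin held a median of 255 to 273 counts, and 11273 of 11579 nuclear bins (97.4%) were kept. Median copy level of whole chromosomes in the G1 libraries lay between 0.948 and 1.02 of the library median, so no chromosome stood out by the size of a gained or lost copy.

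The targeted gene was looked at first. ORC2 (YBR060C) lies on the Crick strand of chromosome II, 360652 to 362514 on sacCer3. Its middle bin, 361001 to 362000, stood above its flanks in all 6 libraries. The growth protocol depletes a product of orc2-1, so these strains held more than 1 form of the gene by construction. In the bin 362001 to 363000, where 514 bases belong to the first 600 coding bases, both libraries labelled orc2ΔN200 lay at single-copy level. Their counts were 0.909 (0.798 to 1.03) and 0.927 (0.808 to 1.06) times the mean of the flanking 20 kb in G1 and S. In the middle bin the same libraries stood at 1.69 and 1.84. The extra copies in these libraries thus lacked the first codons and held later ones, in both cell-cycle phases, as their label states.

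The libraries labelled WT and orc2-I194E did not keep their ORC2 level between G1 and S. In the bin with the first codons, WT went from 2.06 in G1 to 1.66 in S, while orc2-I194E went from 1.38 to 1.97. The counting intervals of the G1 and S values did not overlap under either label. The middle bin showed the same crossing, from 2.63 to 1.81 in WT and from 1.75 to 2.67 in orc2-I194E. LEU2 (YCL018W, chromosome III, 91324 to 92418), a leucine biosynthesis gene widely used as a selection marker, crossed as well. Its first bin stood at 2.57 and 1.73 in WT and at 1.61 and 2.43 in orc2-I194E. A search of 11375 bins for others that crossed in this way by more than 5 counting standard errors found 5 bins in all, every one at ORC2 or LEU2 or in the neighbouring YCL019W. By the same limit, 0 bins separated WT from orc2-I194E in the same direction at both times. The change of residue I194E itself cannot be seen in bin counts. The libraries are therefore named by their labels throughout, and SDs, hill counts, changes at sites, levels at ends and centromeres, region counts and correlations are also given with the 2 labels exchanged at 1 time. Single hills, sites and regions are given as labelled only.

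**Figure D1:**
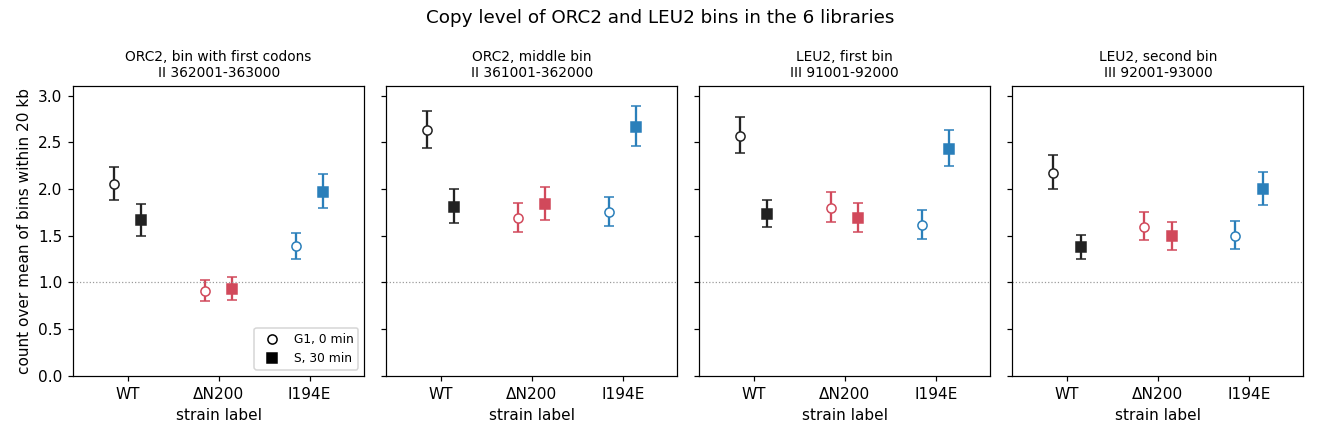
Counts of 4 bins at ORC2 and LEU2 in each library, divided by the mean of the bins within 20 kb (y axis, no unit), for each strain label (x axis), with G1 as open circles, S as filled squares and bars for 95% counting intervals. In the bin with the first ORC2 codons the libraries labelled orc2ΔN200 lay at 0.909 and 0.927, while those labelled WT and orc2-I194E crossed between G1 and S (2.06 to 1.66 and 1.38 to 1.97).

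By 30 min the profile labelled WT showed broad hills and deep valleys of copy number, and those labelled orc2ΔN200 and orc2-I194E were flatter. Valleys were shallower in both mutant profiles, and many broad hills were lower. A smaller set of hills stood as high as in WT or higher. Over bins, the SD of the log2 ratio of S to G1 (5-kb running mean) was 0.168 labelled WT, 0.127 labelled orc2ΔN200 and 0.140 labelled orc2-I194E. The narrower relief of the mutants lay in the low bins. As labelled and in the same order, the 1st percentile of bins was -0.45, -0.25 and -0.27. The 99th was 0.29, 0.33 and 0.38, so the highest bins stood above those of WT. Ratios of 1 G1 library to another, which hold no replication, had SDs of 0.0662, 0.0666 and 0.0695. The slope of the orc2ΔN200 profile on the WT profile was 0.356, and that of orc2-I194E was 0.303, by least squares, which a low correlation also lowers. By the major axis the slopes were 0.565 and 0.617. With the S libraries labelled WT and orc2-I194E exchanged, the SDs became 0.130 for WT and 0.173 for orc2-I194E, so that the orc2-I194E profile was then the one with the deep relief. Exchanging the G1 libraries left WT the highest at 0.173.

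Hills were counted on a 21-kb running mean with a prominence of at least 0.2, a setting chosen after seeing the data. There were 70 labelled WT, 32 labelled orc2ΔN200 and 30 labelled orc2-I194E, against 0, 2 and 0 in ratios of G1 libraries. The planned count, on a 5-kb running mean with a prominence of 0.1, ran the other way, with 462, 553 and 544 peaks, and ratios of G1 libraries had more than any of these. A fixed prominence can pass fewer hills in a flatter profile. With a prominence of 2 SD of each profile, on the 5-kb running mean, there were 79, 77 and 60 peaks. A lower hill count alone thus does not show that hills were lost. At the 70 WT hills the median log2 ratio was 0.17 in WT, 0.020 in orc2ΔN200 and -0.0026 in orc2-I194E. Both mutants lay below WT at 56 of them (80.0%), a share that choosing WT hills gives on its own, as simulated strains with no difference gave 67.7% (49.2% to 85.5% over 100 draws). The median change was -0.12 and -0.15, where the simulation gave -0.030 (-0.048 to -0.014). Simulated strains here and below held counting noise only, with no variation between cultures or in the timing of release. At the 70 WT valleys the medians were -0.30, -0.11 and -0.092, and both mutants lay above WT at 64 (91.4%), where the simulation gave 55.6% (39.3% to 69.2%). The median change there was 0.19 and 0.20, against 0.022 (0.0097 to 0.036) in the simulation. Exchanging the S labels gave 31 hills in WT and 63 in orc2-I194E, and exchanging the G1 labels gave 63 and 31.

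Single hills showed the range of behaviour. The hills and valleys named here were chosen after their values were seen, and picking extremes favours chance ones. On chromosome XV at 441001, next to CKA2, a catalytic subunit of casein kinase 2, a WT hill of 0.21 fell to -0.087 in orc2ΔN200 and -0.14 in orc2-I194E. On chromosome IX at 98001, next to the ribosomal protein gene RPL16A, 0.21 fell to -0.13 and -0.062. The hill over MIS1 on chromosome II at 412001 went from 0.21 to -0.055 and -0.059. Next to the centromere of chromosome III, the hill over SAT4 at 128001 went from 0.23 to -0.029 and 0.0040. The hill next to IML1 on chromosome X at 684001 stood at 0.29, 0.29 and 0.30 in the 3 profiles. The hills so far were hills of the WT profile. Others, called on the orc2ΔN200 profile (SFK1, ATG1) or the orc2-I194E profile (IGD1), stood higher in both mutants. Choosing mutant hills raises mutant values on its own. At 341001 on chromosome XI, over SFK1, WT had 0.062, orc2ΔN200 0.29 and orc2-I194E 0.28. At 162001 on chromosome VII, over the autophagy kinase gene ATG1, the values were 0.15, 0.30 and 0.26. At 182001 on chromosome VI, over IGD1, they were 0.25, 0.33 and 0.43. The orc2ΔN200 hill at MCM7, a gene for a subunit of the helicase that ORC loads, was much alike at 0.14, 0.18 and 0.17. Among valleys, chromosome XII at 858001 over MDM30 rose from -0.45 to -0.038 and 0.014, and chromosome X at 486001 next to GEA1, an activator of Arf GTPases, from -0.46 to -0.16 and -0.17.

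**Figure D2:**
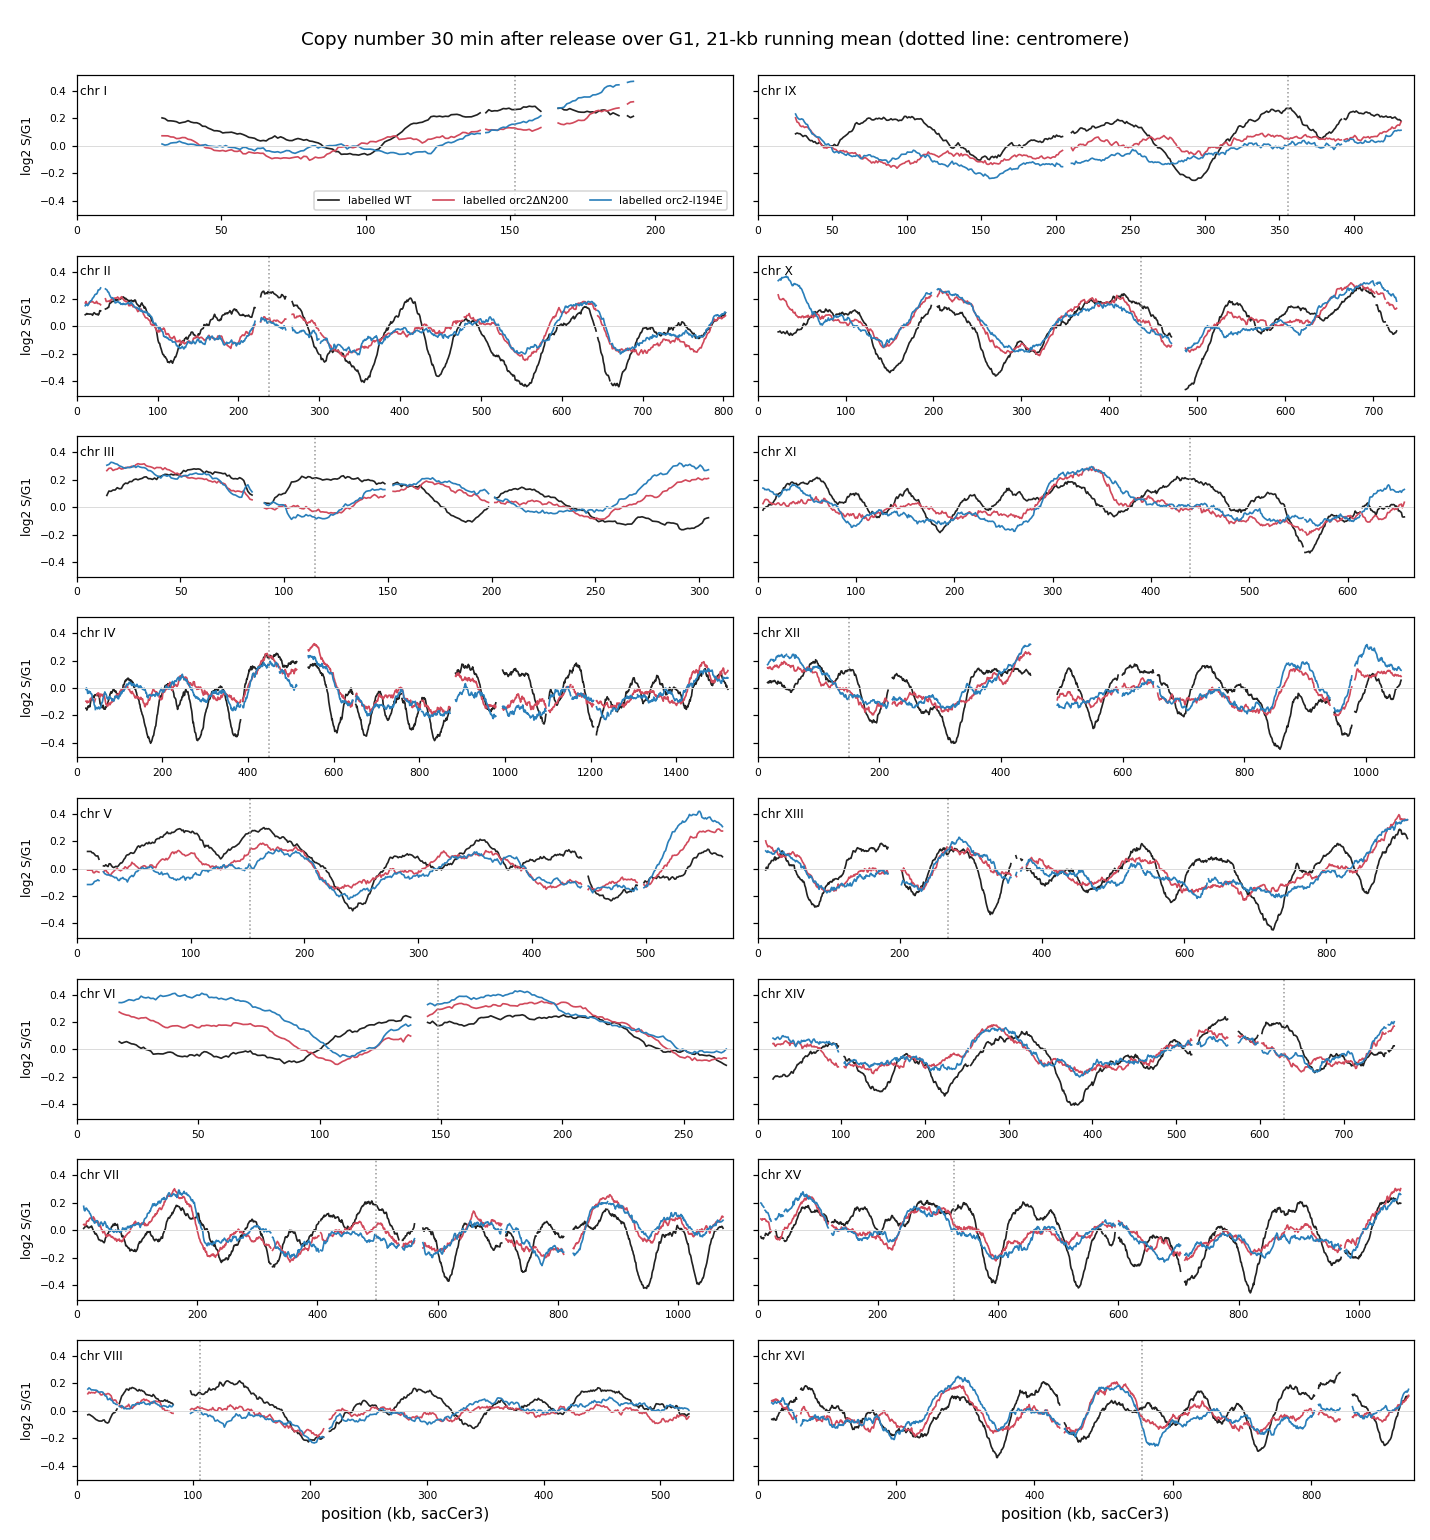
Log2 ratio of the S share to the G1 share (y axis, 21-kb running mean) against position in kb on each of the 16 chromosomes (x axis), 1 line per strain label, with dotted lines at centromeres and gaps where bins were left out. The profile labelled WT had 70 hills, and those labelled orc2ΔN200 and orc2-I194E had 32 and 30.

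Sites of replication were to be compared at annotated origins, but the annotation used names none, so peaks of the WT profile stood in for them as planned. On the planned 5-kb running mean with a prominence of 0.1 these were 462 sites, and heights at them fell in both mutants. The median height was 0.14 labelled WT (0.13 to 0.15), -0.0014 labelled orc2ΔN200 (-0.011 to 0.0079) and -0.026 labelled orc2-I194E (-0.036 to -0.017). Much of this fall comes from the choice of sites. Ratios of G1 libraries had 614, 577 and 606 peaks by the same rule, more than any S profile. The median change was -0.13 in orc2ΔN200 and -0.14 in orc2-I194E, while simulated strains with no difference gave -0.084, with -0.097 to -0.073 over 100 draws. Beyond the counting interval, 195 sites fell and 15 rose in orc2ΔN200, and 207 fell and 22 rose in orc2-I194E. The change of the G1 libraries at the same sites was 0.052 and 0.049. Beyond the counting interval of those ratios, 65 sites were higher and 0 lower for orc2ΔN200 over WT. For orc2-I194E over WT, 66 were higher and 1 lower. An 11-kb window at the WT peaks gave smaller changes, -0.053 and -0.054, and sites from the pooled profile -0.043 and -0.042. Sites taken from the peaks of the other mutant gave changes of 0.011 in orc2ΔN200 and -0.0028 in orc2-I194E, so the fall held for WT peaks and not for those. With the S labels exchanged and the same sites, the changes became -0.034 and 0.042. With the G1 labels exchanged they were -0.081 and -0.042. The simulated fall does not apply to either exchange, as the sites were chosen on the libraries as labelled.

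The highest of these WT sites were chosen by a rule set beforehand, as were those with the largest changes, and both choices favour chance extremes. The site next to PRE5, a proteasome subunit gene on chromosome XIII at 902001, was highest in WT at 0.39 and kept 0.38 in orc2ΔN200 and 0.30 in orc2-I194E. The site over RAD23, a nucleotide excision repair gene on chromosome V at 81001, followed with 0.38 and dropped to 0.16 and -0.064. INP51 on chromosome IX at 352001 went from 0.37 to 0.063 and -0.043, while the site over CDC15, a mitotic exit kinase gene on chromosome I at 174001, went from 0.36 to 0.22 and 0.34. The other 6 of the 10, over or next to GFD2, GLK1, ATP16, GSY1, TFC3 and SEC11, had WT heights down to 0.35. All 10 were lower in orc2ΔN200 than in WT, and 9 in orc2-I194E, the exception being GSY1. The largest fall in orc2ΔN200 was over PEP1, a vacuolar sorting receptor gene on chromosome II at 189001 (-0.46), followed by SHE1, YLR179C, AAC3, ARG1, FAR10, IDP3, SSL2, SGT1 and SLN1. In orc2-I194E it was over YNCP0009W on chromosome XVI at 572001 (-0.48), followed by MUM3, RAD23, COT1, MSA1, SNF2, AAC3, INP51, PMC1 and ERG11. The lists shared 1 site, over the mitochondrial carrier gene AAC3 (chromosome II, 416001), with 0.29, -0.14 and -0.13. The 5 largest rises were at VPS41, ROM2, TRS33, GIT1 and CDC48 in orc2ΔN200, and at ROM2, RPO41, GIT1, LAM5 and TRS33 in orc2-I194E. The site next to ROM2 on chromosome XII at 862001 went from -0.32 to 0.013 and 0.10. The counting standard error of a single change was near 0.077 at the highest sites. TRP1 is the gene beside the well-studied origin ARS1, and no called WT site lay over it. The 5-kb window over it, at 462001 on chromosome IV and chosen after its values were seen, had 0.29, 0.23 and 0.19.

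Over all kept bins, a comparison chosen after seeing the data, chromosome ends and centromeres moved in opposite directions in both mutants. In the profile labelled WT, centromeric DNA stood above the rest of the genome and chromosome ends did not. In the profiles labelled orc2ΔN200 and orc2-I194E the ends stood high and the centromeres had lost most of their excess. Over the 551 kept bins within 30 kb of an end, the median log2 ratio was 0.032 in WT (0.017 to 0.047), 0.11 in orc2ΔN200 (0.098 to 0.13) and 0.14 in orc2-I194E (0.13 to 0.16). Among 10000 rotations of the end positions within each chromosome these lay at percentiles 51.6, 99.99 and 100. Over the 613 bins within 20 kb of a centromere the medians were 0.18 (0.17 to 0.19), 0.042 (0.029 to 0.056) and 0.019 (0.0047 to 0.033), at percentiles 100, 94.5 and 84.5. The G1 libraries differed at ends by -0.0013 for orc2ΔN200 over WT (percentile 40.6) and -0.021 for orc2-I194E over WT (percentile 2.06), and at centromeres by -0.0091 (5.47) and 0.0093 (99.3). The orc2-I194E differences, in the denominator of its ratio, add to the pattern, though they are smaller than it. Among the planned sites, the 30 near centromeres had heights of 0.29, 0.046 and 0.019, and the 21 near ends 0.15, 0.12 and 0.12. As the choice of WT peaks lowers mutant heights on its own, these heights do not tell whether ends rose or fell. Set against all planned sites, the centromeric excess was 0.15, 0.048 and 0.045 and the subtelomeric excess 0.0072, 0.12 and 0.15. Other choices made beforehand moved these: local contrast gave -0.0050, 0.016 and -0.011 for centromeres and 0.041 and 0.027 for mutant ends, and a common G1 denominator gave a WT centromeric excess of 0.091. With the S labels exchanged, WT had 0.13 at ends and 0.029 at centromeres, and orc2-I194E 0.043 and 0.17. With the G1 labels exchanged, WT kept 0.043 and 0.17.

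The shift was spread over most chromosomes. Both mutants lay above WT at 26 of 30 ends with enough bins, where simulated strains with no difference, sharing the same WT libraries, gave a median of 9 (4 to 16 over 100 draws) and independent lists of 26 and 28 ends would share 24.3. Part of the excess over chance can come from the shared WT libraries, which cannot be split. At the left end of chromosome X the values were -0.019, 0.23 and 0.42, and at the right end of chromosome III -0.14, 0.19 and 0.28. The left end of chromosome I went from -0.12 to 0.16 and 0.26. The left end of chromosome V (0.062, -0.035 and -0.092) and the right end of chromosome IX (0.21, 0.094 and 0.058) were lower in both mutants. At centromeres both lay below WT on 15 of 16 chromosomes, where simulation gave 5.5 (2 to 10) and independent lists would share 14.1. Chromosome III had 0.21, -0.0095 and -0.076, and chromosome II 0.25, 0.040 and 0.024. Chromosome VI was the exception by these medians, with 0.21, 0.30 and 0.33. The ends and chromosomes given singly were picked after their values were seen. By the median of bin-by-bin differences from WT, 14 centromeres lay below 0 in orc2ΔN200 and 15 in orc2-I194E. By the same measure 25 and 28 ends lay above 0. Exchanging the S labels left 2 ends above WT and 2 centromeres below it in both mutants, and exchanging the G1 labels left 22 and 13.

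**Figure D3:**
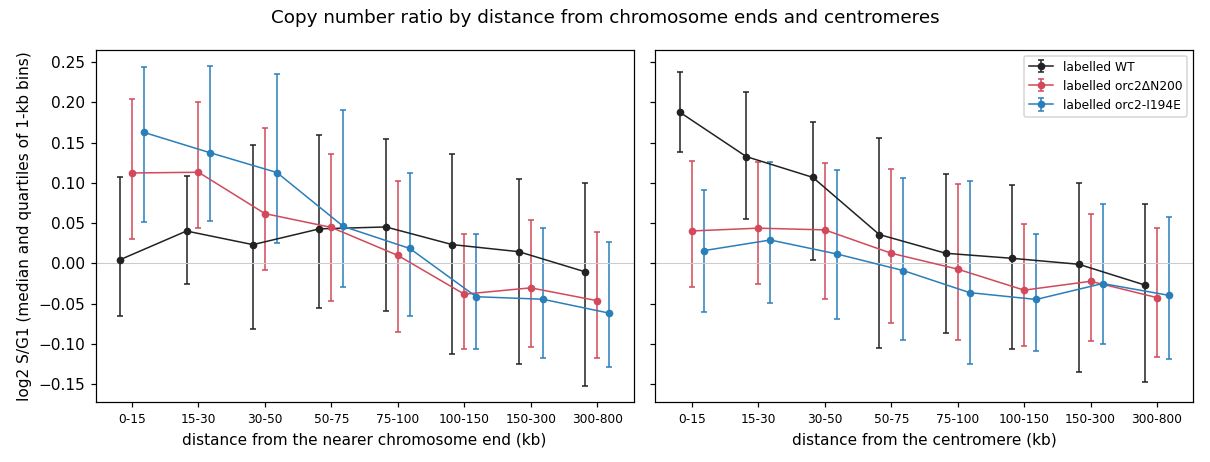
Median log2 ratio of S to G1 (y axis, 5-kb running mean of 1-kb bins, bars from the lower to the upper quartile of bins) by distance in kb from the nearer chromosome end (left panel) and from the centromere (right panel), 1 line per strain label. Within 15 kb of an end the medians were 0.0045, 0.11 and 0.16 for WT, orc2ΔN200 and orc2-I194E, and within 15 kb of a centromere 0.19, 0.040 and 0.016.

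Long stretches of chromosome differed between WT and the mutants. Regions of at least 10 kb where the mean of both mutant profiles departed from WT by 0.15 or more (21-kb running mean) were collected, a search chosen after seeing the data. There were 57 regions higher in the mutants, covering 1463 kb, and 49 lower, covering 1375 kb. Among the higher ones, that at 348001 to 369000 on chromosome II held the ORC2 bins, whose copy level crossed between G1 and S. The same search over G1 libraries found 0, and strains simulated with counting noise only gave at most 1. Neither covers variation between cultures in S phase. Regions that were higher had a median of -0.29 in WT, -0.048 in orc2ΔN200 and -0.054 in orc2-I194E, and 7 of them lay within 30 kb of an end. Regions that were lower had 0.15, -0.049 and -0.075, and 8 of them held a centromere, against 0 of the higher ones. The longest on the higher side, 76 kb, ran from 17001 to 93000 on chromosome VI, a stretch that holds the actin gene ACT1 at its middle, with -0.035, 0.17 and 0.35. A region of the same length on chromosome XII, 841001 to 917000 around CSR1, had -0.24, 0.038 and 0.10. Near the right end of chromosome III, 270001 to 305000 around CDC50 had -0.12, 0.14 and 0.26. On the lower side, 994001 to 1064000 on chromosome IV around GCN2, a kinase gene of translational control, had 0.10, -0.11 and -0.17. On chromosome IX, 61001 to 124000 around TMA108 had 0.17, -0.10 and -0.083. A region over the centromere of chromosome XI, 419001 to 463000 around the dynamin-like gene VPS1, had 0.19, -0.019 and 0.018. Exchanging the S labels left 13 higher and 23 lower regions, and exchanging the G1 labels 55 and 50.

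The mutant profiles, set side by side because one lacks the stretch in which the other has a changed residue, were much alike. Hills of one often lay at hills of the other, and the relief was shared along every chromosome. Differences between them were few. Across bins of the 21-kb running mean, which are not independent, Pearson's r was 0.882 between the mutants, 0.565 between orc2ΔN200 and WT and 0.443 between orc2-I194E and WT. Simulated strains with no difference gave 0.964. Across the 462 sites r was 0.761, 0.486 and 0.411, with Spearman's rho of 0.729, 0.482 and 0.424. On 16 of 16 chromosomes the mutants correlated best with each other, with r from 0.755 to 0.924. Of the 32 hills of orc2ΔN200, 17 lay within 10 kb of a hill of orc2-I194E (1.71 for random positions), and 17 lay within 10 kb of a WT hill (4.04 for random positions). With the S labels exchanged, orc2ΔN200 correlated with WT at 0.884 and with orc2-I194E at 0.598. With the G1 labels exchanged the values were 0.598 and 0.884.

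Between the mutants, the planned sites differed by 0.014 (0.0021 to 0.025), and 417 of 462 lay within the counting interval of the difference. Beyond it, 21 were higher and 24 lower in orc2ΔN200. The ratio of their G1 libraries had 34 and 19 sites beyond its own interval. The difference of orc2ΔN200 minus orc2-I194E was -0.032 at ends and 0.032 at centromeres. Part of it lies in the G1 libraries. Ends minus centromeres was 0.070 in orc2ΔN200 and 0.13 in orc2-I194E with each mutant's own G1 library. With the G1 library labelled WT for both it was 0.070 and 0.097. Regions of at least 10 kb that differed by 0.15 or more numbered 2 with orc2ΔN200 higher and 5 with orc2-I194E higher, against 0 between their G1 libraries. With the S labels exchanged the difference became 0.069 at ends and -0.12 at centromeres, with 55 and 43 such regions. With the G1 labels exchanged it was -0.0026 and 0.019, with 1 and 6. Around SPF1, an ATPase gene of the endoplasmic reticulum on chromosome V (82001 to 104000), orc2ΔN200 had 0.11 and orc2-I194E -0.068, with 0.27 in WT. Around MET30 on chromosome IX (261001 to 280000) they had 0.054 and -0.13. The region with the largest excess in orc2-I194E lay on chromosome VI (29001 to 71000) around FET5, with 0.38 against 0.18 in orc2ΔN200 and -0.035 in WT. On chromosome X (27001 to 53000) around CBP1, orc2-I194E had 0.32 and orc2ΔN200 0.12. Around the calcineurin gene CNA1 on chromosome XII (993001 to 1017000) they had 0.28 and 0.087. The remaining ones lay around BRR2 on chromosome V (520001 to 545000) and PCK1 on chromosome XI (622001 to 643000). The search was chosen after seeing the data.

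**Figure D4:**
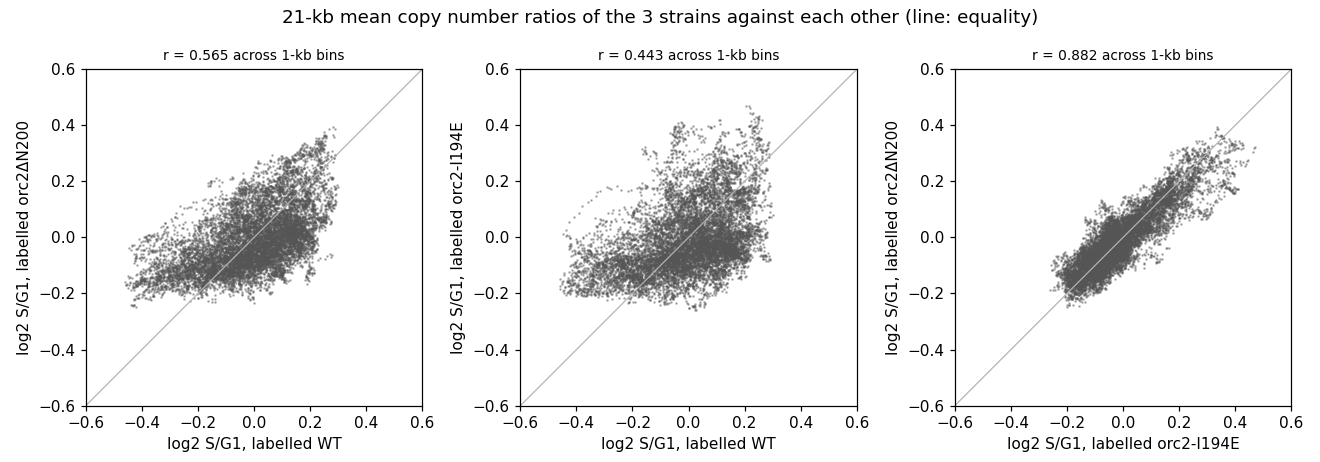
Log2 ratios of S to G1 (21-kb running mean, 1 point per 1-kb bin) of each strain label against another, with axes from -0.6 to 0.6 and a line of equality. The points of the 2 mutant labels lay closest to a line (r = 0.882), against 0.565 and 0.443 for orc2ΔN200 and orc2-I194E with WT.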

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

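All tests of explanations in this part were chosen only after the result was seen. None of the differences between strain labels given here was tested across samples, and each label had 1 library per time.

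The ribosomal DNA, as measured in 2 bins, gained copies relative to the rest of the genome in the profiles labelled orc2ΔN200 and orc2-I194E. It lost share in that labelled WT. It was singled out because WT lay on one side of 0 and both mutants on the other, a difference that was not tested. The 2 bins (459001 to 461000 on chromosome XII) were those of the array with a high count in every library. They hold the gene RDN5-1 and an end of RDN37-2, and so stand for part of the repeat only. Their log2 ratio of S to G1 was -0.067 in WT (-0.096 to -0.038), 0.26 in orc2ΔN200 (0.24 to 0.29) and 0.30 in orc2-I194E (0.27 to 0.33). Both bins went the same way under each label. With the S libraries labelled WT and orc2-I194E exchanged, WT would have 0.24 and orc2-I194E -0.0021, and with the G1 libraries exchanged -0.0021 and 0.24, so which labels gained depends on the labels. No explanation was tested for it.

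LEU2 carried more counts than its flanks in all 6 libraries, a signal outside the planned measurement. Its first bin stood at 2.57 and 1.73 times the flanks in G1 and S labelled WT, at 1.80 and 1.69 labelled orc2ΔN200, and at 1.61 and 2.43 labelled orc2-I194E. The libraries labelled orc2ΔN200 kept their level between the times and the other labels crossed, as at ORC2.

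The first pattern weighed is the crossing of ORC2 copy level between G1 and S in the libraries labelled WT and orc2-I194E. Replication timing of the native locus on chromosome II cannot account for it, as its flanks replicate at about the same time. Relative to them the level changed by -0.43 in WT (-0.56 to -0.30) and 0.56 in orc2-I194E (0.43 to 0.69). Both changes lie beyond a bound of 0.2 on the log2 scale. The extra copies may lie elsewhere in the genome. Their own replication timing cannot be judged against these flanks, so it stays open. If the labels were exchanged at 1 time, the S library labelled orc2-I194E against the G1 library labelled WT would differ by -0.016 (-0.13 to 0.10), within that bound. The other exchanged pair, S labelled WT against G1 labelled orc2-I194E, would differ by 0.15 (0.0071 to 0.29), which the bound leaves undecided. An exchange is thus a candidate explanation. Extra copies that differed between the G1 and S samples of a strain cannot be told apart from it with 1 library per strain and time. Such copies would have to change in opposite directions under the 2 labels, at both ORC2 and LEU2. Neither the time nor the direction of an exchange can be read from these counts.

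The second pattern is the opposite movement of chromosome ends and centromeres over all kept bins, singled out because WT and both mutants lay on opposite sides of 0, a difference that was not tested. The level at ends minus that at centromeres was -0.15 in WT (-0.17 to -0.13), 0.070 in orc2ΔN200 (0.051 to 0.090) and 0.13 in orc2-I194E (0.10 to 0.15). The tables argue against a bias of the mutants' own G1 libraries, since with the G1 library labelled WT as denominator the values were 0.070 and 0.097, and against poorly mapped bins at ends, since bins with G1 counts near the median gave 0.077 and 0.11 (WT -0.15). What stays open is the label: with the S libraries labelled WT and orc2-I194E exchanged, WT would have 0.097, so that only orc2ΔN200 and WT would share the pattern. A difference between the Orc2 forms, which the design names, and a bias of the S libraries by base composition both remain untested.

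The third pattern is that the mutant profiles resembled each other more than WT. A flatter copy of the WT profile with independent counting noise would leave a partial correlation given WT near 0 once the counting noise of WT is taken out, yet it was 0.853 over bins (0.731 to 0.946 over single chromosomes). Taking out G1 coverage instead left 0.85 against 0.854 without it, a term that moves so little that it was no test of a bias of the S libraries. Another sampling point in an S phase with the WT order of replication would keep ends below centromeres, and they lay above by 0.070 in orc2ΔN200 and 0.13 in orc2-I194E. What stays open is such a bias, a departure of the WT libraries beyond counting noise, an exchange of the S labels, which would make WT and orc2ΔN200 the alike pair (0.884, while an exchange of the G1 labels would not), and, untested, a difference between the Orc2 forms.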

How the results depend on the processing

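The exchanges of labels, the 21-kb settings, and sites from pooled or mutant profiles were chosen after seeing the data, and the others before. No paired analysis was run, with 1 library per strain and time. The GC correction was not run, as no genome sequence was used here. Of the values recomputed with choices set before, 80 stayed within counting error, or within 1.5 times for a count, 73 moved and 4 changed sign from a value whose counting interval excluded 0. Another 9 among those that stayed or moved changed sign from a value whose interval held 0. With later ones 25 stayed, 28 moved, 4 changed sign from outside such an interval and another 2 from within one. Sign changes from within an interval were those of the orc2ΔN200 height (-0.0014) and the WT subtelomeric excess (0.0072). Values are given as WT, orc2ΔN200 and orc2-I194E where there are 3, and as orc2ΔN200 and orc2-I194E where there are 2. Except where a construction is named, the cause was not tested.

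The change of height at WT peaks is lowered by the choice of sites in each setting that keeps them, so its sign carries little weight, and its size followed the window and scale. With 1 bin per site the WT height was 0.12, the orc2ΔN200 change -0.11 and the WT excess of subtelomeric sites -0.043, the last with another sign. An 11-kb window gave a WT height of 0.066 and changes of -0.053 and -0.054. Scaling to the 10th percentile, which raises all heights by construction, gave 0.38, 0.15 and 0.14, both mutant heights changing sign, and changes of -0.22 and -0.21. Relative to the library median, the mutant heights were 0.0096, with another sign, and -0.012, and the changes -0.12 and -0.12. Profiles scaled to the same SD gave changes of -0.79 and -0.86 SD. Local contrast gave mutant heights of 0.010 and 0.00070, both changing sign, and an orc2ΔN200 change of -0.12. Under it the subtelomeric excess was 0.041 and 0.027, and the centromeric excess -0.0050, 0.016 and -0.011, changing sign in WT and orc2-I194E, as neighbouring DNA is subtracted.

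A common G1 denominator gave heights of 0.16, 0.011 (with another sign) and -0.0019, changes of -0.12 and -0.12, an SD of 0.165 in WT and 0.129 in orc2-I194E, slopes of 0.414 and 0.340, 305 WT peaks, a WT centromeric excess of 0.091, and correlations of 0.560 (orc2ΔN200 with WT) and 0.821 (between mutants).

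Without smoothing the SDs were 0.206, 0.176 and 0.186 and the slopes 0.237 and 0.196. An 11-kb mean gave SDs of 0.160, 0.118 and 0.131, slopes of 0.388 and 0.337, and 154, 139 and 152 peaks. The distance from the 10th to the 90th percentile was 0.434, 0.328 and 0.359. WT kept the widest relief in each.

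Peak counts followed the threshold, and their order between strains changed with it. A prominence of 0.05 gave 883, 1010 and 1000 peaks, 0.2 gave 158, 149 and 163, and 2 SD of the profile gave 79, 77 and 60. A 3-kb mean gave 961, 1063 and 1063. The 21-kb mean gave 108, 58 and 59 at a prominence of 0.1, where ratios of G1 libraries gave 65, 55 and 62. At 0.2 it gave 70, 32 and 30. Within 2 kb of a WT peak lay 18.3% and 16.2% of mutant peaks and within 10 kb 68.7% and 68.8%, against 42.0% and 39.9% within 5 kb. No share for random positions was set beside these, and it rises with the distance allowed. They therefore do not tell whether mutant peaks lay near WT peaks more often than random positions do. Narrower classes, 15 kb from an end and 10 kb from a centromere, gave a subtelomeric excess of 0.21 in orc2-I194E. Across all kept bins orc2-I194E correlated with WT at 0.364, and in the 21-kb mean orc2ΔN200 correlated with WT at 0.565 and with orc2-I194E at 0.882.

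The change also moved with the choice of sites. Sites from the pooled profile gave mutant heights of 0.068 and 0.057, both changing sign, and changes of -0.043 and -0.042. Sites from the 21-kb WT profile with a prominence of 0.2 gave 0.15, 0.021 and 0.022, both mutant heights changing sign, and an orc2ΔN200 change of -0.11. Sites from the other mutant's profile gave changes of 0.011, with another sign, and -0.0028.

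Exchanging the G1 libraries labelled WT and I194E gave changes of -0.081 and -0.042 and SDs of 0.173 in WT and 0.130 in orc2-I194E. Exchanging the S libraries gave changes of -0.034 and 0.042, the latter changing sign, SDs of 0.130 and 0.173, a subtelomeric excess of 0.14 in WT and 0.018 in orc2-I194E, a centromeric excess of 0.075 and 0.13, and correlations of orc2ΔN200 of 0.759 with WT and 0.490 with orc2-I194E.

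Copy levels at ORC2 relative to the library median were lower in S than relative to flanks, as the flanking bins lay below the library median there. Relative to flanks, the bin with the first codons stood at 1.66 in S labelled WT and 1.97 in S labelled orc2-I194E (1.40 and 1.79 by the median), and the middle bin at 1.81, 1.84 and 2.67 in S (1.52, 1.65 and 2.42). Depth limits single sites, where a change carried a counting standard error near 0.079, and not medians over sites.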

Other observations

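Whole chromosomes differed in their ratio of S to G1 at 30 min, which is relative to the genome mean of each profile. Shorter chromosomes tended to stand higher. Spearman's rho of length with the ratio of S to G1 across chromosomes was -0.83 labelled WT, -0.75 labelled orc2ΔN200 and -0.54 labelled orc2-I194E. Chromosome VI, among the shortest, stood highest of all chromosomes in both mutant profiles, and not in that labelled WT. Its median log2 ratio of S to G1 was 0.090, 0.16 and 0.26 for WT, orc2ΔN200 and orc2-I194E. Chromosome I had 0.16 labelled WT, 0.070 labelled orc2ΔN200 and 0.026 labelled orc2-I194E. Chromosome IV, the longest in the bins used, had -0.042, -0.051 and -0.056 for WT, orc2ΔN200 and orc2-I194E. These chromosomes were chosen after their values were seen, and their values are as labelled.

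The mitochondrial genome, copied independently of nuclear origins, made up 11.2% (G1) and 9.68% (S) of counts labelled WT, 7.95% and 9.25% labelled orc2ΔN200, and 9.69% and 9.88% labelled orc2-I194E. Relative to kept nuclear bins, the log2 ratio of S to G1 was -0.23, 0.24 and 0.033. With the S libraries labelled WT and orc2-I194E exchanged, WT would have -0.20 and orc2-I194E -0.0013, and with the G1 libraries exchanged -0.0013 and -0.20. It was not used in the profiles.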
